A study of Arabidopsis thaliana with 9 samples.

How the data were processed

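Total RNA of seedlings of 3 genotypes was extracted with TRIzol and sequenced as paired reads on a NovaSeq instrument, with 3 libraries per genotype. The labels do not state how RNA was selected for the libraries, and they name the source as genomic although the assay is RNA-seq. According to the authors, reads were converted with bcl2fastq, aligned with HISAT2 to TAIR10 and processed with edgeR, without versions, a counting tool, an annotation or strandedness being given. The deposited signal values are read counts that edgeR had adjusted to a common library size (its quantile-to-quantile pseudo-counts), which was read from the values and not from a statement by the authors. They are not raw counts, not scaled to CPM and not divided by gene length.

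The table held 32548 genes, all of which matched an identifier in the TAIR10.1 reference annotation, and 25179 of them had reads. Whole read counts were recovered by inverting the adjustment with a relative size per library and a dispersion of 0.00826 per genotype: 99.9993% of the values were whole at a tolerance of 0.01 reads or a relative 1e-05, and 2 values were not. The fitted sizes lay within 1.05% of TMM sizes. The recovered totals, given with the results, set the counting floors of 3 counts and the 95% exact binomial intervals, and the 10 most abundant genes took 7.54% to 9.57% of the reads of a library. The table held 0 organellar genes and 4 ribosomal RNA genes.

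The design written before the data were examined named the edgeR quasi-likelihood test with TMM factors for counts and limma-trend for FPKM, TPM or CPM. The deposited values are none of these, so the main test was a choice that the design did not settle. As they are not raw counts, limma-trend (limma 3.58.1 in R 4.3.3) was applied to log2(value + 1). It covered the 23207 genes with a value of at least 1 in 3 or more libraries. One model of the group means covered all 9 libraries, with 6 residual degrees of freedom. The contrasts were al24567 minus Col-0, ring1a1b minus Col-0 and ring1a1b minus al24567, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. Errors of log2 fold changes are the moderated standard errors of that model.

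The 17 gene lists, of 300 genes, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 on the same log2 values, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The direction of a list is that of its test, and the value given for it is the median log2 fold change of its tested members. The symbols of 297 list genes were found in the reference, and the other 3 (BMI1B, BMI1C and TIP3;2) are known there under other names. Named genes followed a fixed rule. For each mutant against Col-0 it took the 9 disrupted and family genes, the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap and whose mean was at least 2 CPM, and up to 4 called members per list with the smallest p, or the member with the smallest p where none was called. It took 4 rises and 4 falls for ring1a1b minus al24567, and 5 genes in each direction and up to 5 in opposite directions for both mutants. Genes without room were left to counts.

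The alternatives were a pseudocount of 0.1, no filter, a minimum of 5 CPM in 3 libraries, the table without ribosomal RNA genes, only the 2 genotypes compared, replicate number as a block, a 2-fold minimum, an adjusted p below 0.01, each library left out, and 3 tests on the recovered counts: edgeR 4.0.16 with RLE size factors, DESeq2 1.42.0 and limma-voom. A pair of alternatives was chosen after seeing the data: the edgeR quasi-likelihood test with TMM factors on the recovered counts, and deposited values rescaled to equal totals. The former is the test that the design named for counts. In the count tests and the fits of 2 genotypes, lists were tested with cameraPR on the z-scores of the genes.

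The calling was tested on simulated data with 50 changed genes per fold. For al24567 it found 5, 34, 44 and 50 genes at 1.25-fold, 1.5-fold, 2-fold and 4-fold, with 4 unchanged genes among 137 calls. For ring1a1b it found 7, 36, 41 and 50, with 9 unchanged genes among 143 calls. Far fewer genes changed in the simulations than were called in the data, so these rates do not carry over to the data. Overlap of the mutant comparisons was set beside 20 simulations of unchanged groups against shared controls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Without a stated strand, reads of overlapping genes on opposite strands cannot be told apart, and values of near-identical copies (LHCB1, RBCS, the 2S albumins, PDF1, KIN1 and KIN2, COR15A and COR15B) may exchange reads.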

Results

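RNA was sequenced from 11-day-old Arabidopsis seedlings of 3 genotypes, with 3 libraries each. Col-0 is the wild type. The line al24567 carries homozygous mutations in AL2, AL4, AL5, AL6 and AL7, members of the ALFIN-like family of plant homeodomain proteins, which bind histone H3 methylated at lysine 4. The line ring1a1b carries homozygous mutations in RING1A and RING1B, RING finger proteins of Polycomb repressive complex 1, which ubiquitinates histone H2A. The read totals recovered from the deposited table were 19284453, 18559959 and 22435655 reads in Col-0 replicates 1 to 3. They were 20293181, 18258434 and 18768791 reads in al24567, and 19773247, 19569172 and 18291449 reads in ring1a1b. At these depths a gene without reads in a library could lie at up to 0.134 to 0.164 CPM, from 3 counts over the library total; such limits and all counting intervals cover counting error only. Values below are the deposited adjusted read counts, as mean ± SD, and log2 fold changes are given ± SE from the limma fit, with n = 3 libraries per genotype throughout. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Libraries of one genotype correlated at 0.980 to 0.985 across genes and libraries of different genotypes at 0.941 to 0.967, and the first principal component held 46.2% of the variance.

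The targeted genes differed in how far their transcripts were reduced. In al24567, 4 of the 5 targeted AL genes fell, while AL5 was not called. In ring1a1b, RING1A transcripts were nearly lost and RING1B transcripts fell less. AL2 (AT3G11200; TAIR10.1 annotation, chromosome 3, 3507996 to 3510658) had a value of 884 ± 43.6 in Col-0 and 137 ± 18.4 in al24567, and fell by 2.69 ± 0.10 on the log2 scale. AL4 (AT5G26210; chromosome 5, 9158318 to 9160493) fell by 1.74 ± 0.10, AL6 (AT2G02470; chromosome 2, 652564 to 654985) fell by 1.72 ± 0.13, and AL7 (AT1G14510; chromosome 1, 4961594 to 4964515) fell by 1.95 ± 0.13. AL5 (AT5G20510; chromosome 5, 6939813 to 6943011) stood at 92.0 ± 6.59 in Col-0 and 88.4 ± 1.04 in al24567, a log2 difference of -0.06 ± 0.18 (adjusted p = 0.844). The family members that were not targeted, AL1 (0.00 ± 0.09) and AL3 (-0.08 ± 0.07), were not called in al24567. RING1A was not called there either (0.09 ± 0.38), while RING1B rose by 0.73 ± 0.20 (adjusted p = 0.00663, limma). Together, 1 of these 9 genes rose and 4 fell in al24567 (camera adjusted p = 0.00976; adjusted p = 0.253 with an estimated correlation). The list includes the genes mutated in these lines, so a fall is built in and its test adds no support in either mutant.

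In ring1a1b, RING1A (AT5G44280; chromosome 5, 17835810 to 17839303) went from 148 ± 15.6 in Col-0 to 1.33 ± 1.56 and fell by 6.23 ± 0.38. RING1B (AT1G03770; chromosome 1, 944572 to 947682) went from 107 ± 23.1 to 61.0 ± 8.97 and fell by 0.79 ± 0.20. AL4 fell by 0.36 ± 0.10 and AL5 rose by 0.53 ± 0.18, whereas AL1 (-0.13 ± 0.09), AL2 (-0.05 ± 0.10), AL3 (-0.03 ± 0.07), AL6 (-0.13 ± 0.13) and AL7 (-0.08 ± 0.13) were not called. With library totals made equal, the differences of AL2 and AL3 turned to 0.01 and 0.02, and that of AL1 in al24567 to -0.04. So 1 of the 9 genes rose and 3 fell (camera adjusted p = 0.0402; adjusted p = 0.160 with an estimated correlation). The list's call was lost without Col-0 replicate 3 (0.0571), without ring1a1b replicate 3 (0.0641), with a pseudocount of 0.1 (0.0777), with a minimum of 5 CPM (0.105) and by limma-voom (0.0735). The call of RING1B was lost without Col-0 replicate 2 (adjusted p = 0.0560), that of AL4 with equal totals (0.0701) or without Col-0 replicate 1 (0.10), Col-0 replicate 3 (0.0560), ring1a1b replicate 2 (0.0596) or ring1a1b replicate 3 (0.0591), and that of AL5 without a filter (0.0544), with replicate number as a block (0.0532) or without Col-0 replicate 1 (0.0873), Col-0 replicate 2 (0.143), Col-0 replicate 3 (0.0838), ring1a1b replicate 1 (0.165) or ring1a1b replicate 2 (0.157).

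**Figure D1:**
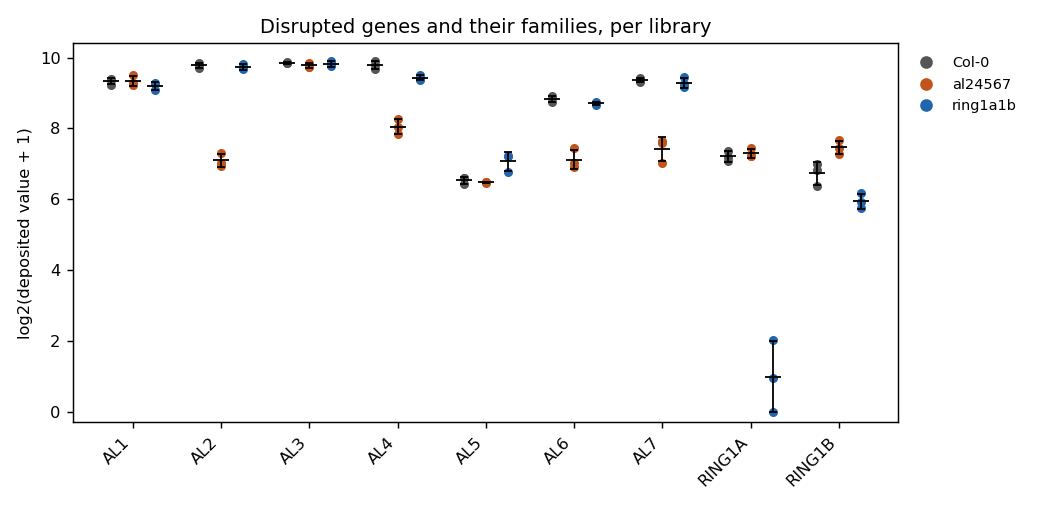
Deposited value of each ALFIN-like and RING1 gene as log2(value + 1) in each library, by genotype; dots are libraries and bars are the mean ± SD, n = 3. In al24567, AL2 averaged 137 against 884 in Col-0, and in ring1a1b RING1A averaged 1.33 against 148.

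The comparison of al24567 with Col-0 asks which transcripts depend on the 5 ALFIN-like genes. Of 20 tested genes of salicylic acid defence 17 rose, and of 11 jasmonate and ethylene defence genes 6 rose and 1 fell. With an estimated correlation neither list was called (adjusted p = 0.292 and adjusted p = 0.493). The defensin genes PDF1.2, PDF1.3 and PDF1.4 rose. Transcripts of the flowering promoters SOC1 and FUL, of the cold-regulated genes COR15A and COR15B and of the embryo patterning gene WOX2 fell. The largest rise was that of CYP82C2 (AT4G31970; chromosome 4, 15462350 to 15464563), a cytochrome P450, from 16.9 ± 15.4 to 1573 ± 238, a log2 fold change of 6.78 ± 0.50. The largest fitted fall was that of QQS (AT3G30720; chromosome 3, 12349047 to 12349933), a gene that affects starch content, from 371 ± 56.4 to 1.78 ± 1.28, which fell by 7.14 ± 0.31. AT5G42280 had 0 reads in al24567, so its fall has only a lower bound and cannot be ranked against that of QQS.

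Of 23207 genes tested by limma, 8432 differed between al24567 and Col-0 at an adjusted p below 0.05, with 4163 higher (49.4%) and 4269 lower in the mutant; the share higher was 43.8% with library totals made equal and 52.7% by DESeq2. Of these, 1060 were at least 2-fold higher and 853 at least 2-fold lower. Among the 8 largest rises were also NATA1 (5.70 ± 0.85), an acetyltransferase, TAT3 (4.02 ± 0.66), a tyrosine aminotransferase, GPT2 (4.02 ± 0.51), a plastid glucose 6-phosphate carrier, and the receptor-like kinase gene CRK13 (3.93 ± 0.37). The defensin genes PDF1.3 (5.46 ± 0.65), PDF1.2 (5.02 ± 0.77) and PDF1.4 (3.82 ± 0.28) completed that group; reads of near-identical defensin copies could not be told apart here. Among the largest falls, AT5G42280, a gene for a C1 domain protein on chromosome 5 (16905202 to 16908059), had 0 reads in the 3 al24567 libraries and 116 ± 11.2 in Col-0, at least 110-fold lower from a floor of 3 counts over the group. AT1G64795 (-5.86 ± 0.55), AT3G23480 (-4.91 ± 0.25), LBD26 (-4.83 ± 0.53), the actin family gene AT2G42170 (-4.76 ± 0.33), PORA (-4.70 ± 0.39), which encodes a protochlorophyllide oxidoreductase, and AT3G50560 (-4.69 ± 0.27) followed. Without Col-0 replicate 2 or replicate 3, NATA1 stood at 7.24 or 4.57, TAT3 at 5.18 or 2.94 and PDF1.2 at 5.70 or 4.02; CYP82C2 stood at 7.44 without Col-0 replicate 3, PDF1.3 at 6.05 without Col-0 replicate 2 and PORA at -4.08 without al24567 replicate 1. For these 16 genes no al24567 library overlapped a Col-0 library, as the rule for choosing them required; by chance 10% of genes would separate in this way with 3 against 3.

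Of the 20 tested salicylic acid genes, 17 rose and 3 were not called, with a median log2 fold change of 1.32 (camera adjusted p = 1.32e-09; adjusted p = 0.292 with an estimated correlation). ACD6 rose by 1.81 ± 0.11, PR5, a pathogenesis-related protein gene, by 1.67 ± 0.18, the transcription factor gene WRKY38 by 3.24 ± 0.41, and EDS1, a regulator of resistance, by 0.76 ± 0.08. Of 11 jasmonate and ethylene genes, 6 rose, 1 fell and 4 were not called, with a median of 1.13 (camera adjusted p = 0.0109; adjusted p = 0.493 with an estimated correlation). The jasmonate synthesis genes AOS (1.21 ± 0.08) and LOX2 rose, as did the repressor gene JAZ1 (0.77 ± 0.12); VSP1, named after its value was seen, was the member that fell (-0.81). The jasmonate call was lost with a minimum of 5 CPM in 3 libraries (adjusted p = 0.133). Of 7 senescence genes, 4 rose, 1 fell and 2 were not called (camera adjusted p = 0.115, and adjusted p = 0.00540 by DESeq2): SAG13 (3.20 ± 0.16), ORE1 (0.88 ± 0.12) and WRKY6 (0.77 ± 0.10) rose, and NAP fell by 0.83 ± 0.08. Of 7 heat shock genes, HSP90.1 rose (0.70 ± 0.10) and 6 were not called (camera adjusted p = 0.317).

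Of 20 flowering time genes, 3 rose, 7 fell and 10 were not called (camera adjusted p = 0.229). SOC1, a promoter of flowering, went from 917 ± 72.6 to 258 ± 27.2 and fell by 1.83 ± 0.10. The floral repressor gene MAF2 fell by 0.69 ± 0.10, while the repressor genes TEM1 (1.01 ± 0.07) and MAF5 (2.07 ± 0.28) rose. Of 14 floral homeotic and flower MADS genes, 3 rose, 5 fell and 6 were not called (camera adjusted p = 0.50); their median was 0.14, whereas their mean (-0.13) and the test pointed down, and the median was -1.49 by edgeR. FUL (-2.84 ± 0.41), SEP4 (-2.43 ± 0.18) and AGL24 (-1.41 ± 0.24) fell, and SEP3 rose by 1.52 ± 0.36. The 3 rises were 1 by edgeR and by DESeq2 and 2 by limma-voom. Of 13 meristem and boundary genes, 2 rose, 1 fell and 10 were not called (camera adjusted p = 0.968), with a median of 0.04 and a mean of -0.17; the median was -0.10 by edgeR. The boundary gene CUC3 fell by 2.49 ± 0.45. Of 14 embryo and seed maturation regulators, 5 fell and 9 were not called (camera adjusted p = 0.210), among them WOX2 (-2.79 ± 0.36), which patterns the early embryo, the dormancy gene DOG1 (-2.87 ± 0.39) and AIL5 (-0.88 ± 0.23). Of 20 storage, oil body and late embryogenesis genes, 5 rose, 1 fell and 14 were not called (camera adjusted p = 0.311). LEA4-5 (1.24 ± 0.27) and OLEO4 (1.13 ± 0.31) rose, and OLEO2, with 0 reads in Col-0, was at least 7.25-fold higher.

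Of 20 abscisic acid, cold and drought genes, 4 rose, 9 fell and 7 were not called (camera adjusted p = 0.179). The cold-regulated genes COR15B (-3.07 ± 0.17), COR15A (-1.17 ± 0.13) and KIN2 (-0.51 ± 0.09) fell, as did the alcohol dehydrogenase gene ADH1 (-1.06 ± 0.16). Of 22 cell cycle and DNA replication genes, 8 fell and 14 were not called, with a median of -0.26 (camera adjusted p = 0.0353; adjusted p = 0.529 with an estimated correlation). CDC20.1, an activator of the anaphase-promoting complex, fell by 0.74 ± 0.13, the cytokinesis gene KNOLLE by 0.59 ± 0.12, and the replication helicase genes MCM7 (-0.42 ± 0.10) and MCM5 (-0.44 ± 0.11) also fell. The cell cycle call was lost without Col-0 replicate 3 (adjusted p = 0.0733), al24567 replicate 1 (0.0578) or al24567 replicate 3 (0.110), by DESeq2 (0.0741) and with the minimum of 5 CPM (0.0715).

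The list named for H3K4 methylation, H3K27 demethylation and H2A.Z had 21 tested genes. Of these, 1 rose, 8 fell and 12 were not called (camera adjusted p = 0.101). The list holds both methyltransferase and demethylase genes, and also histone deacetylase, H2B ubiquitination and deubiquitinase genes. Its counts therefore do not measure a single process. The methyltransferase genes ATXR7 (-0.49 ± 0.09) and SDG8 (-0.33 ± 0.08), the H2B ubiquitin ligase gene HUB2 (-0.38 ± 0.09) and the demethylase gene JMJ18 (-0.46 ± 0.11) fell. Of 19 Polycomb genes, 4 fell and 15 were not called (camera adjusted p = 0.459). EMF1 fell by 0.83 ± 0.10. By edgeR, DESeq2 and limma-voom 3 fell. In limma, the call of VIN3, with 8 reads in Col-0, was lost without Col-0 replicate 2 (adjusted p = 0.0751) or 3 (0.0837). That of VAL3 was lost without Col-0 replicate 1 (0.0933) or al24567 replicate 1 (0.12). EMF2 lost its call without Col-0 replicate 1 (0.111), al24567 replicate 2 (0.0563) or 3 (0.0623), and by DESeq2 (0.0512). Of 18 root markers, 8 rose, 3 fell and 7 were not called (camera adjusted p = 0.179): PRP3 (1.09 ± 0.14), EXPA18 (0.89 ± 0.15) and SCR (0.41 ± 0.08) rose and GL2 fell by 0.56 ± 0.10. Of 34 photosynthesis genes, LHCB1.4 fell by 0.60 ± 0.12 and 33 were not called by limma (camera adjusted p = 0.659); edgeR called 2 lower, limma-voom 5 lower, and DESeq2 3 lower and 2 higher. Of 3 tested pollen markers, HAP2 was called lower by limma (-1.68) and 2 were not called (camera adjusted p = 0.473). By edgeR, DESeq2 and limma-voom 0 were called, against 1 at an unadjusted p below 0.05 in limma. The call of HAP2 was lost without Col-0 replicate 2 (adjusted p = 0.0577), Col-0 replicate 3 (0.101) or al24567 replicate 2 (0.121), by DESeq2 (0.137) and with only the 2 genotypes compared (0.0507). Adjusted over the list alone, the counts of all 17 lists in al24567 were the same except for 5 rises among the abscisic acid genes and 2 falls among the senescence genes. Other tools gave fewer or more calls in some lists: edgeR called 2 rises among the abscisic acid genes, limma-voom 3 rises among the storage genes and 2 falls among the senescence genes, DESeq2 1 fall among the root markers and edgeR 2. Among the storage genes 1 fell by limma-voom, as by limma, and 0 fell by edgeR or DESeq2 (1 at an unadjusted p below 0.05 in limma).

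The comparison of ring1a1b with Col-0 asks which transcripts depend on the RING1 proteins. Seed transcripts were present in these seedlings: 15 of 20 tested storage, oil body and late embryogenesis genes rose, several from no reads in Col-0, together with the maturation regulator ABI3 and 13 of 20 abscisic acid, cold and drought genes. The Argonaute genes AGO5 and AGO9 rose from at most 3 reads in Col-0. Of 20 salicylic acid defence genes 9 fell, among them PR1. AGO9 (AT5G21150; chromosome 5, 7192239 to 7198381) stood at 861 ± 86.8 in ring1a1b, and its ratio to the 3 reads in Col-0 was 892 (95% counting interval 305 to 4330).

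Of the 23207 genes, 4111 differed between ring1a1b and Col-0, with 2331 higher (56.7%) and 1780 lower in the mutant. With library totals made equal, 69.8% of the called genes were higher, and with a minimum of 5 CPM in 3 libraries 49.3% were, with 1650 higher and 1700 lower. Of the called genes, 1002 were at least 2-fold higher and 264 at least 2-fold lower. AGO5 (AT2G27880; chromosome 2, 11871378 to 11876989) stood at 680 ± 23.0, 1057 times (292 to 8738) the 2 reads in Col-0. AT1G74140, for a rhomboid-related protease, stood at 424 ± 57.3 with a ratio of 659 (182 to 5451), and the late embryogenesis gene AT4G36600 at 385 ± 52.3 with a ratio of 399 (136 to 1937). AT3G15670 rose by 7.56 ± 0.46. CRC (AT4G28520; chromosome 4, 14087556 to 14089796), a cruciferin storage protein gene, had 0 reads in Col-0 and 856 ± 721 in ring1a1b, at least 901-fold higher; EM1 (AT3G51810; chromosome 3, 19214722 to 19215831) was at least 504-fold higher and BGLU19 at least 294-fold higher. Replicate 3 of ring1a1b held a CRC value of 85.1 against 1514 and 970 in the others. The calls of CRC and BGLU19 were lost by edgeR (adjusted p = 0.0539 and 0.0596), and that of CRC by limma-voom (0.112). After RING1A itself, the largest falls were AT1G64795 (-5.87 ± 0.55), PR1 (-4.95 ± 0.65), the non-coding RNA gene AT3G06955 (-4.21 ± 0.25), AT2G15042 (-3.55 ± 0.22), the lipid transfer protein gene LTP4 (-3.42 ± 0.41), the methyltransferase gene FAMT (-3.41 ± 0.33) and PCR1 (-3.33 ± 0.48). Without ring1a1b replicate 2 or replicate 3, PR1 stood at -6.24 or -3.97 and PCR1 at -4.03 or -2.65. The fitted log2 fold change of CRC was 8.97, and 8.18 or 10.24 without ring1a1b replicate 1 or 3; that of BGLU19 was 7.62, and 6.98 or 8.59 without ring1a1b replicate 2 or 3. That of AGO9 was 9.11, and 9.73 without Col-0 replicate 3.

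Of the 20 storage, oil body and late embryogenesis genes, 15 rose and 5 were not called. Their median log2 fold change was 3.91, or 3.95 with genes at 0 reads in a group set to their bounds. The camera adjusted p was 1.43e-18, and 0.0779 with an estimated correlation. The oleosin gene OLEO2 was at least 182-fold higher, the peroxiredoxin gene PER1 at least 153-fold higher, and ECP63 rose by 5.03 ± 0.41. The median was 7.13 with the minimum of 5 CPM and 6.25 by edgeR. Of 14 embryo and seed maturation regulators, 7 rose and 7 were not called (camera adjusted p = 0.00510; adjusted p = 0.0779 with an estimated correlation). ABI3 stood at 35.7 ± 8.78 against 2 reads in Col-0, a ratio of 55.4 (15.0 to 463), and DOG1 (2.63 ± 0.39), AIL5 (1.57 ± 0.23) and AGL15 (1.52 ± 0.29) rose. This call was lost with the minimum of 5 CPM (adjusted p = 0.168). Of 20 abscisic acid, cold and drought genes, 13 rose and 7 were not called, with a median of 0.54 (camera adjusted p = 6.58e-11; adjusted p = 0.0779 with an estimated correlation). RD29B averaged 126 in Col-0 and 2586 in ring1a1b and rose by 4.34 ± 0.31, and COR15A (1.46 ± 0.13), KIN2 (0.81 ± 0.09) and COR47 (0.60 ± 0.06) rose.

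Of 20 salicylic acid genes, 9 fell, 1 rose and 10 were not called, with a median of -0.50 (camera adjusted p = 7.43e-07; adjusted p = 0.195 with an estimated correlation). PR1 fell from 1028 ± 285 to 73.6 ± 104, and ACD6 (-1.61 ± 0.11), WRKY70 (-1.54 ± 0.13), WRKY54 (-2.24 ± 0.26) and SARD1 (-1.63 ± 0.21) fell; SAG101, named after its value was seen, rose (0.41). The median was -0.27 without Col-0 replicate 2. Of 20 flowering time genes, 6 rose and 14 were not called (camera adjusted p = 0.0181; adjusted p = 0.105 with an estimated correlation). The members with the smallest p encode repressors of flowering: SNZ rose by 1.04 ± 0.10, MAF5 by 2.64 ± 0.28, MAF4 by 2.44 ± 0.32 and TEM1 by 0.40 ± 0.07. Of 34 photosynthesis genes, 3 fell and 31 were not called (camera adjusted p = 0.00685; adjusted p = 0.600 with an estimated correlation; adjusted p = 0.0913 by fry), with RBCS1B, a Rubisco small subunit gene, at -0.46 ± 0.09.

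Of 19 Polycomb genes, 5 rose, 2 fell and 12 were not called (camera adjusted p = 0.346), with a median of -0.03 (0.03 with equal totals) and a mean of 0.50. The genes of the BMI1 family, RING finger partners in the same complex, rose: BMI1A by 1.38 ± 0.11, BMI1B by 0.79 ± 0.13, and BMI1C to 101 ± 7.38, a ratio of 104 (35.4 to 509) to the 3 reads in Col-0. The fitted log2 fold change of BMI1C was 5.98, and 6.66 without Col-0 replicate 2. EMF1 fell by 0.43 ± 0.10. The 21 tested genes of the list named for H3K4 methylation, H3K27 demethylation and H2A.Z were not called (camera adjusted p = 0.346). ATX2 stood at -0.23 ± 0.10. In limma 3 members were lower at an unadjusted p below 0.05, and 0 were called by edgeR, DESeq2 or limma-voom. The 11 jasmonate and ethylene genes were not called either (camera adjusted p = 0.866), with a median of 0.00 and a mean of -0.23; 0 passed at an unadjusted p below 0.05 or in the other tools. JAZ5 stood at 0.69 ± 0.34 and was called without Col-0 replicate 1 (1.09, adjusted p = 0.0355).

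Of 7 heat shock genes, 4 rose, 1 fell and 2 were not called (camera adjusted p = 0.0846), with HSP18.2 at 1.35 ± 0.21 and HSP17.6II at 22.7 times (7.44 to 113) its 3 reads in Col-0; the list was called without Col-0 replicate 1 (adjusted p = 0.0425) or ring1a1b replicate 2 (0.0377). Of 7 senescence genes, 2 rose, 2 fell and 3 were not called (camera adjusted p = 0.866): SEN1 rose by 1.36 ± 0.15, and SAG13 fell by 1.38 ± 0.16. Of 14 floral homeotic and flower MADS genes, 1 rose, 3 fell and 10 were not called (camera adjusted p = 0.486), with a median of 0.04 and a mean of -0.12, and a median of -0.42 by edgeR; AGL24 fell by 1.67 ± 0.24 and SEP4 by 0.93 ± 0.18. Of 18 root markers, 3 rose and 15 were not called (camera adjusted p = 0.137), and the nitrate transporter gene NRT2.1 was among the rises; the list was called without ring1a1b replicate 1 (adjusted p = 0.0447). Of 13 meristem and boundary genes, 1 rose and 12 were not called (camera adjusted p = 0.191), and of 22 cell cycle genes CYCD3;1 rose by 0.44 ± 0.10 and 21 were not called (camera adjusted p = 0.866). The 3 tested pollen markers were not called (camera adjusted p = 0.447; 0 at an unadjusted p below 0.05 in limma, and 0 by edgeR, DESeq2 or limma-voom). Adjusted over the list alone, the counts in ring1a1b were the same except for 1 fall among the embryo regulators, 7 rises among the flowering time genes, 2 falls among the photosynthesis genes, 14 rises among the abscisic acid genes and 3 falls among the senescence genes. Among the photosynthesis genes 4 fell by edgeR, 6 by DESeq2 and 5 by limma-voom, and among the meristem genes 2 rose by edgeR and by limma-voom.

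**Figure D2:**
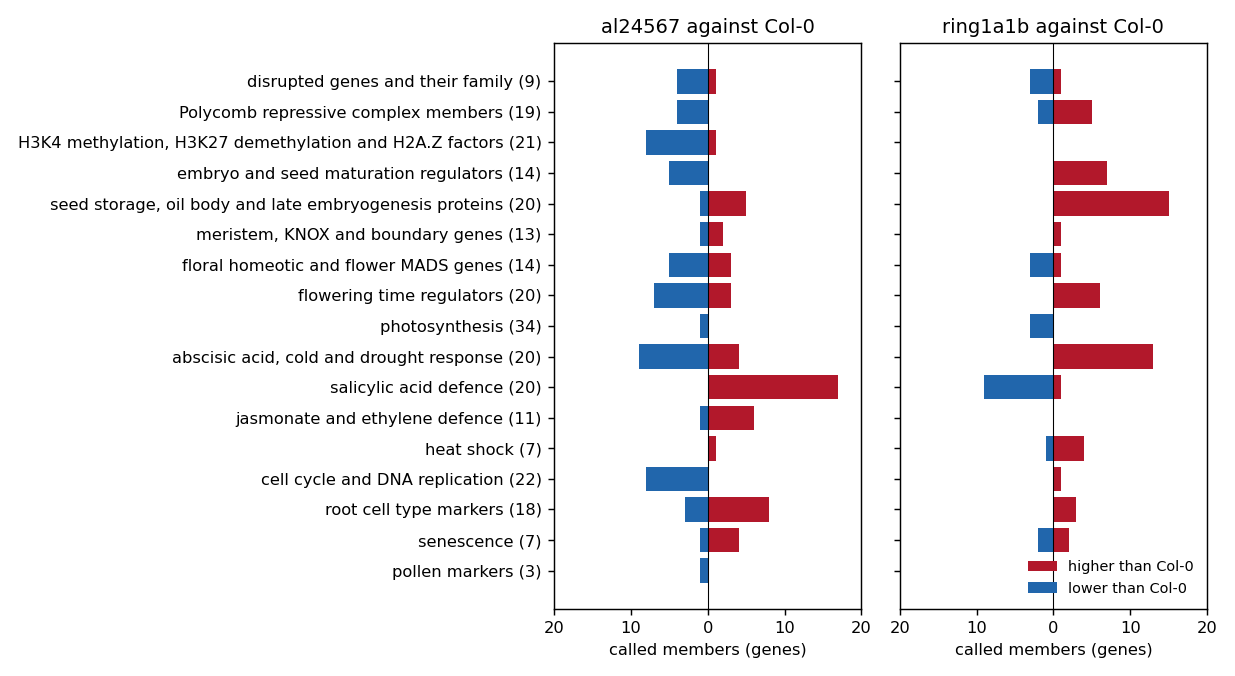
Number of members called higher or lower in each of the 17 fixed gene lists, for al24567 and for ring1a1b against Col-0, with the number of tested members in brackets. In the salicylic acid list 17 members were higher in al24567 and 9 were lower in ring1a1b; in the storage list 15 were higher in ring1a1b.

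The direct comparison of ring1a1b with al24567 tests where the mutants differ. Salicylic acid genes were lower in ring1a1b than in al24567 for 18 of 20 members, with a median difference of -2.08, while storage protein genes were higher for 16 of 20, with a median of 4.33. With an estimated correlation neither list was called (camera adjusted p = 0.092 for each). AGO5 had 680 ± 23.0 in ring1a1b and 0 reads in al24567, at least 648-fold higher. AT5G42280 was at least 349-fold higher in ring1a1b, CRC had 829 times (283 to 4021) the 3 reads of al24567, and AT1G74140 had 606 times (168 to 5012) its 2 reads. CYP82C2 (-7.64 ± 0.50), PR1 (-7.31 ± 0.65), PDF1.3 (-6.66 ± 0.65) and RING1A (-6.31 ± 0.38) were lowest in ring1a1b relative to al24567. Without ring1a1b replicate 2 or replicate 3, PR1 stood at -8.60 or -6.34 and PDF1.3 at -7.44 or -5.89; CYP82C2 stood at -8.33 without ring1a1b replicate 2. By limma, 9040 genes differed, with 4652 higher (51.5%) and 4388 lower in ring1a1b, and 65.0% were higher with library totals made equal. With the minimum of 5 CPM 47.0% were higher, with 3417 higher and 3850 lower. Of the 9040 genes, 1781 were at least 2-fold higher and 1032 at least 2-fold lower. The call of CRC in this comparison was lost by limma-voom (adjusted p = 0.0982), and its fitted log2 fold change of 8.29 was 8.94, 7.49 and 9.56 without al24567 replicate 1, ring1a1b replicate 1 and ring1a1b replicate 3.

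In this comparison 7 of the 17 lists were called: storage proteins (camera adjusted p = 3.32e-09), abscisic acid, cold and drought (3.08e-07, 13 higher and 1 lower of 20), embryo regulators (0.00241, 8 higher and 1 lower of 14), flowering time (0.00875, 9 higher and 2 lower of 20), salicylic acid (7.50e-15), jasmonate and ethylene (0.00717, 1 higher and 7 lower of 11) and the cell cycle (0.0325, 9 higher of 22). With an estimated correlation the adjusted p was 0.0921 for the first 5 of these lists and 0.280 and 0.517 for the last pair. The other 10 lists were not called: disrupted genes (camera adjusted p = 0.0914), Polycomb members (0.143), H3K4 and H2A.Z factors (0.243), meristem genes (0.303), floral genes (0.805), photosynthesis (0.121), heat shock (0.796), root markers (0.670), senescence (0.177) and pollen markers (0.211). The floral list (median -0.35, mean 0.01) and the heat shock list (median -0.33, mean 0.78) had a test that pointed up, and the disrupted genes had a median of 0.59 and a mean of 0.02. The call of the cell cycle list was lost without al24567 replicate 1 (adjusted p = 0.0548), al24567 replicate 3 (0.119), ring1a1b replicate 1 (0.0678) or ring1a1b replicate 3 (0.0570), and by DESeq2 (0.0733). With the minimum of 5 CPM, the embryo (0.191) and jasmonate (0.145) calls were lost, and the photosynthesis list was called without al24567 replicate 2 (0.00834). By DESeq2 the disrupted genes (adjusted p = 0.000125) and the senescence list (adjusted p = 0.00286) were called.

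The question of what the mutants share was asked on the genes called in both. The oxygenase gene DIN11 and the acyltransferase gene AACT1 rose in both mutants, and QQS, the thionin gene AT1G66100 and AT1G64795 fell in both. Other genes moved in opposite directions: DOG1, AT1G09500, AT4G22390 and MES18 fell in al24567 and rose in ring1a1b, and AT5G24200 rose in al24567 and fell in ring1a1b. DIN11 rose by 3.07 ± 0.31 in al24567 and 3.21 ± 0.31 in ring1a1b, and AACT1 by 3.37 ± 0.33 and 2.99 ± 0.33. AGO9 had 8.34 times (2.52 to 43.4) the reads of Col-0 in al24567, with a fitted log2 fold change of 2.53 (3.16 without Col-0 replicate 3), and OLEO2 was at least 7.25-fold and at least 182-fold higher. In al24567 and ring1a1b, AT1G64795 stood at -5.86 ± 0.55 and -5.87 ± 0.55, AT1G66100 at -3.40 ± 0.15 and -2.79 ± 0.15, QQS at -7.14 ± 0.31 and -2.75 ± 0.31, AT2G15042 at -2.34 ± 0.22 and -3.55 ± 0.22, and AT1G64360 at -3.91 ± 0.28 and -2.31 ± 0.28. DOG1 stood at -2.87 ± 0.39 in al24567 and 2.63 ± 0.39 in ring1a1b. AT1G09500 stood at -2.47 ± 0.22 in al24567 and 3.24 ± 0.22 in ring1a1b; AT4G22390 had 0.0320 times (0.000787 to 0.191) the reads of Col-0 in al24567 and rose by 3.76 ± 0.40 in ring1a1b. MES18 had 0.0119 times (0.00143 to 0.0436) the reads of Col-0 in al24567 and rose by 2.36 ± 0.38 in ring1a1b, a call lost with a pseudocount of 0.1 (adjusted p = 0.0631). AT5G24200 stood at 2.96 ± 0.61 in al24567 (3.72 without Col-0 replicate 2) and -2.52 ± 0.61 in ring1a1b (-1.81 without ring1a1b replicate 3). Its call in ring1a1b was lost without Col-0 replicate 2 (-1.76, adjusted p = 0.0545), by edgeR with TMM (adjusted p = 0.0577) or RLE factors (adjusted p = 0.0576), and by limma-voom (adjusted p = 0.0562).

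In all, 2251 genes were called in both mutants, of which 831 were higher in both, 807 were lower in both and 613 moved in opposite directions. At a change of at least 2-fold in both, the numbers were 362, 149, 61 and 152. Independent lists of these sizes would share 418 higher and 327 lower genes and hold 748 in opposite directions. Both comparisons use the same Col-0 libraries, and 3 controls cannot be divided into sets of at least 2, so unchanged groups against shared controls were simulated 20 times. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.145 (0.495 in the simulation) and a Spearman correlation of 0.237 (0.447 in the simulation). Their covariance was 0.0748 against 0.0422 in the simulation. The simulated groups held no changed genes, so their correlations reflect the shared controls alone. Correlations of data with many changed genes cannot be ranked against them. In the simulation, where calls are rare by construction, at most 1 gene was higher in both, and 0 were lower in both or opposite. The count of genes in both was 1497 without Col-0 replicate 1, that of genes lower in both was 445 without Col-0 replicate 1 and 493 without Col-0 replicate 3, and that in opposite directions was 373 without Col-0 replicate 2. The count of genes lower in ring1a1b was 1103 without Col-0 replicate 1, 1183 without Col-0 replicate 3 and 1166 without ring1a1b replicate 3.

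**Figure D3:**
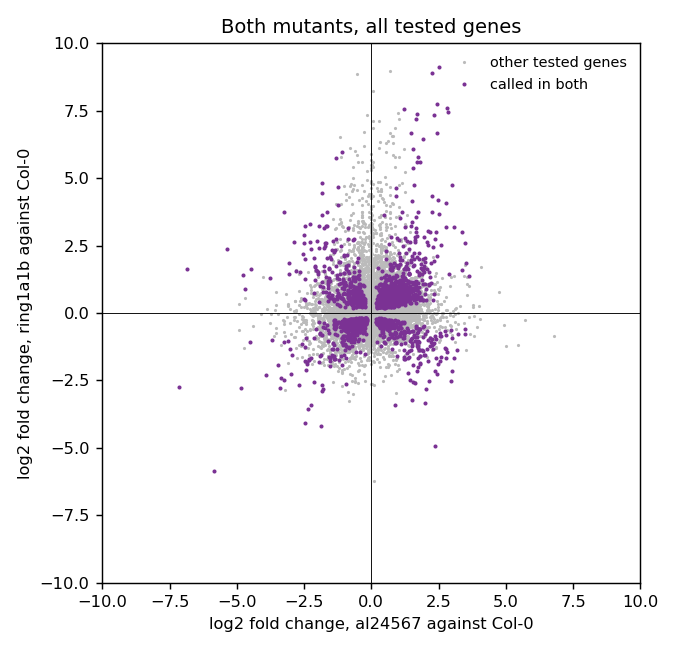
Log2 fold change against Col-0 in al24567 (x axis) and in ring1a1b (y axis) for each tested gene; purple points are the 2251 genes called in both mutants. Of these, 831 lie above 0 on both axes, 807 below 0 on both, and 613 have opposite signs.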

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

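The difference between the mutants was tested directly, by the contrast ring1a1b minus al24567, as planned; the test on the storage genes' libraries below was chosen after the values were seen. By camera with a preset correlation, 7 lists differed between the mutants. With a correlation estimated per list, 0 of the 17 lists were called (camera in limma; 5 at an unadjusted p below 0.05, and 12 lists by fry). The median difference in log2 fold change was 4.328 for seed storage, oil body and late embryogenesis genes, 1.211 for embryo and seed maturation regulators, 0.738 for abscisic acid, cold and drought genes, 0.553 for flowering time regulators and 0.311 for cell cycle genes. It was -2.075 for salicylic acid genes and -1.087 for jasmonate and ethylene genes.

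Of the 10 splits of 6 libraries into groups of 3, only 1 gave as many genes in each comparison, the real one, with 8432 genes in al24567, 4111 in ring1a1b and 9040 between the mutants; the highest of the other splits called 0 genes in each. For lists, 2 of 10 splits gave as many in al24567 (4 lists, highest other 4), 1 of 10 in ring1a1b (7, highest other 5) and 2 of 10 between the mutants (7, highest other 7). With 10 splits the share is never under 0.1. Every other split puts libraries of both genotypes in each group, which widens the spread within groups. Its 0 genes were thus nearly fixed in advance and say little about chance. For the genes called in both mutants, 2 of 100 drawn splits of the 9 libraries gave as many as the real 2251; the other one called 4327 genes with the 3 al24567 libraries as controls and Col-0 and ring1a1b libraries mixed, which points to the structure of the samples.

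Storage protein genes were uneven among the ring1a1b libraries. The 13 list members examined were called higher in ring1a1b and had a mean there of at least 20. Their log2 ratio of replicate 3 to the mean of the other libraries had a median of -0.40. It ran from -3.85 for CRC to 0.69 for PAP85. If one material of fixed makeup, such as seed tissue, were present at a varying share, these ratios would be alike. Instead 4 members (30.8%) lay more than 1 from the median, against 0 for replicate 1 over replicate 2. Replicate 3 and the limit of 1 were chosen after these values were seen, and PAP85 passed the limit narrowly. CRC (-3.85), TIP3;1 (-2.17) and CRA1 (-2.05) lay furthest out. The ratios of replicate 3 were thus not alike. As the test was fitted to these values and rests on replicate 3 alone, it cannot decide whether a single such material was present. A varying mixture of tissues and a change within the seedlings' cells may both remain, and no test here separates them.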

How the results depend on the processing

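The equal totals and the use of the edgeR test with TMM factors on the recovered counts were chosen after seeing the data. The design had named this edgeR test for counts. No direction of a called result was reversed under any alternative run. For the 164 called results of named genes, 3425 of 3565 values kept the call and 140 lost it. For the 18 called lists, among them the disrupted genes in each mutant, 378 of 432 values kept the call and 54 lost it. For the 33 lists without a call, 26 of 780 values gained one. Of 332 values for counts, 300 stayed within 1.5 times. Over all settings, 6 values of named genes changed sign and 28 values of lists changed the direction of the test, each called neither with all libraries in limma nor under the setting. Shared with limma's calls were 8066, 3642 and 8339 genes by edgeR (95.7%, 88.6% and 92.2%) for al24567, ring1a1b and ring1a1b minus al24567. The table without ribosomal RNA genes lost 3 tested genes and so tests little. Between genotypes, same-numbered libraries had a mean correlation of 0.039 (-0.053 to 0.151), and other pairs -0.02 (-0.172 to 0.067). A weak pairing by replicate number therefore cannot be excluded. With it as a block, 8574 genes were called in al24567, 4305 in ring1a1b and 9176 between the mutants, against 8432, 4111 and 9040. Among named genes the block ended only the call of AL5 in ring1a1b (adjusted p = 0.0532, limma). With equal totals, 1156 genes were lower in ring1a1b, which follows from the rescaling. A 2-fold minimum, which by construction lowers counts, left 1913 genes in al24567 (1060 higher, 853 lower), 1266 in ring1a1b (1002, 264), 2813 between the mutants (1781, 1032), 362 in both (149 higher, 61 lower, 152 opposite) and 7 lists. An adjusted p below 0.01 left 2838 lower in al24567, 2366 in ring1a1b (1503, 863) and 1111 in both (468, 342, 301 opposite). Of 18 list calls, 0 held with an estimated correlation (12 at an unadjusted p below 0.05) and fry called 34, since fry does not compare a list with other genes. With the minimum of 5 CPM, the floral list was called in al24567 (0.0464) and ring1a1b (0.0136), and by DESeq2 the senescence list in al24567 (0.00540) and, between the mutants, the disrupted genes (0.000125) and the senescence list (0.00286); the cause was not tested. With 1 library left out, a group has fewer samples: genes lower in ring1a1b ranged from 1103 to 2012, genes in both from 1497 to 2333, genes lower in both from 445 to 864 and those in opposite directions from 373 to 643. Named genes with a call ranged from 153 to 163 (164 with all libraries) and list calls from 16 to 19. Of 50 genes simulated at the smallest fold tried, 5 were found for al24567 and 7 for ring1a1b. Far fewer genes changed there than were called in the data, which makes the adjusted p stricter. These rates do not carry over to the data, where called changes were as small as 0.162 (log2) in al24567 and 0.185 in ring1a1b. Depth was not varied, so depth and the spread between libraries cannot be separated here as limits. Replicates differed beyond counting noise (chi-square per gene 3.68 to 10.8), so counting alone does not account for their spread.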

Other observations

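The genes, classes and tests in this part were chosen after their values were seen, except the tests on overlapping genes, on segments around AL genes and on the upper limits of read ratios, which were chosen before their results were seen. In ring1a1b, 69 genes had at most 3 reads in Col-0 and at least 1 CPM in every mutant library, and 10 of them are in the fixed lists, 8 in the storage list. Besides AGO5, AGO9 and ABI3 they include the chromatin remodelling gene PKR2 (mean value 184 against 0.638), the B3 transcription factor gene REM1 (106 against 1.04), the F-box gene AT1G27580 (214 against 0.906), ULT2 (26.1, no reads in Col-0), AOX2 (46.4 against 0.344) and the late embryogenesis genes AT4G21020 (168), AT1G72100 (161) and AT5G44310 (117), which had no reads in Col-0. In al24567, 15 of the 69 were called higher and 54 were not called, beside 4163 called higher among all 23207 tested genes. With at most 3 reads in the shared Col-0 libraries, these genes could hardly be called lower.

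In al24567, 1 gene was on by the same limits, CHX2 (38.2 against 0.692), and 6 were off: AT5G42280, the methyl esterase genes MES8 (0.339 against 27.6) and MES18 (0.719 against 59.7), GER2 (0.70 against 30.3), and the F-box genes AT1G78750 (0.704 against 48.7) and AT5G56370 (0.677 against 39.0). Of 80 tested microRNA genes 1 was higher and 7 were lower in al24567.

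Of 620 long non-coding RNA genes, 64 fell and 6 rose in al24567, with a median log2 fold change of -0.20, while of 22187 protein-coding genes 4182 fell and 4137 rose. Protein-coding genes matched on value had a median of -0.03 and 0% of 1000 draws were as low, which argues against low abundance. Matched also on length, for short transcripts, their median was -0.002 and again 0% were as low. All 3 tested ribosomal RNA genes rose in al24567. The labels do not state how RNA was selected, and its part in the non-coding falls was not tested. Among 198 that overlap no other gene 30 fell and 2 rose; their median was -0.199, and 2.8% of draws were as low, just inside the middle 95% (-0.202 to 0.06), so reads of overlapping genes counted without strand may still contribute.

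In al24567, 16 genes were at least 16-fold lower. For chromosome segments around the disrupted AL genes, 1 of them lay within 1 Mb of an AL gene, as in the median random draw (79.6% of draws had as many), which argues against such segments as the cause of the group. The genes lie on 4 chromosomes and the largest set joined in steps of 1 Mb holds 3 of them, which argues against one linked segment as the cause of the whole group. In all 3 pairs lay within 1 Mb, against a median of 2 and an upper limit of 6 in random draws (37.8% had as many), so linked segments behind part of the group stay open. The highest upper limit of the read ratios was 0.119, a limit that choosing genes by a 16-fold fall keeps low by itself. In 20 redistributions of the reads of all 23207 tested genes by counting error alone, at most 0 genes had such a fall. With 1 added to each value, few reads can hardly give such a fall, so that count was nearly fixed in advance. It shows only that counting error alone does not reach falls of this size.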
